A study of Mus musculus with 13 samples.

How the data were processed

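Alveolar macrophages were sorted from the lungs of each of 13 mice, and polyadenylated RNA was made into libraries with NEBNext Ultra I kits from 100 ng of RNA with an integrity number over 7. Libraries were read as 75 bp single ends on a NextSeq instrument, with over 94% of bases at Q30. By the submitters' processing notes, reads were demultiplexed with bcl2fastq (version 2.19), aligned to mm10 with TopHat2, counted per gene with HTSeq and tested with edgeR. The deposited table holds, per the file headers, 1 row for each of 43430 genes with a raw read count for each library in the unit "count", and the gene coordinates in the file (Start, End and Length, the unit "other") were used here only for positions and overlaps. The values were whole numbers, as the unit asks. Annotation release and strand setting of the counting were not given in the sources used here. Of the gene IDs, 42462 had a symbol in the name table, and 40355 of these lay on the same chromosome with a nearby start in GENCODE release M21. The kit keeps no strand, so counts of genes that overlap another counted gene are uncertain; among those named in the text these are Aars, Abcc1, Bhlhe40, Cd74, Cep55, Clspn, Col4a1, Crem, Cyfip2, Ddit3, Dnaja1, Ear1, Ephx1, Fkbp5, Gclm, Gpr171, Herpud1, Hmcn1, Hspa1a, Il1a, Il1b, Jun, Junos, Kif14, Klf9, Lss, Me1, Mertk, Ndrg1, Orai1, Ppp1r15a, Prr33, Saraf, Sesn2, Slc11a2, Slc1a3, Slc2a1, Slc30a1, Slc39a2, Slc7a11, Sparcl1, Srebf1, Syvn1, Thbs1, Timp3, Tiparp, Top2a and mt-Nd4.

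The main analysis used R 4.3.3 and edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which kept 11906 genes, and libraries were scaled with the trimmed mean of M values. A quasi-likelihood model with 1 coefficient per group (9 residual degrees of freedom, a median of 10.2 prior degrees of freedom, a common biological coefficient of variation of 0.0635) gave 7 comparisons. They were PM against PBS within each drinking-water arm, metformin against vehicle within each instillate, the difference of the PM effects, and the PM and metformin effects averaged over the other factor. P values were adjusted with the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are called. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F, and ranges and SDs refer to libraries. Principal components were taken from log2 CPM with a prior count of 2. Depth per library is given with the results.

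The comparisons, the naming rule, the alternatives and 34 gene lists were set before the data were examined. Of 971 gene names in the lists, 965 matched a single ID. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Members were also adjusted over each list alone. The lymphocyte, eosinophil, and erythroid and platelet lists were too small for the list test. Named genes are, for each comparison, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted and unnamed genes (for the difference and the averaged effects the overlap rule was not used), up to 4 members of each list with the lowest adjusted p, and a preset panel of inflammatory, antioxidant, metal, aryl hydrocarbon receptor, coagulation and calcium entry genes. Not all of the genes the rule allows are printed, and some single genes are not reported here. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, no or a stricter filter (5 CPM in 3 libraries), a fit with only the groups compared, the replicate number of the titles as a block, and leaving out each library. Thinning of every library to equal totals was added after the data were seen. Group labels were also moved between libraries in all 35 or 10 splits of the simple comparisons and in 100 splits for the others.

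The pipeline was tested on simulated data with known changes. For PM with vehicle it called 45 of 66 genes changed 1.5-fold, 59 of 66 changed 2-fold and 65 of 66 changed 4-fold, and for the difference 33 of 67, 51 of 67 and 64 of 66. Small differences of the PM effect are therefore often missed at this depth and number of animals. Of the genes called in the simulation, unchanged genes made up 3.98% for PM with vehicle and 5.06% for PM with metformin, but 8.11% for metformin with PBS, 7.78% for metformin with PM, 7.5% for the difference, 8.54% for PM averaged and 7.22% for metformin averaged. In 6 of the 7 comparisons this share lay above the 5% the threshold allows on average. Figures were drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. No library of the deposited table was left out of the main analysis, and alignments and reads were not analysed here.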

Results

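Polyadenylated RNA was sequenced from alveolar macrophages, the resident phagocytes of the airspaces, isolated by flow cytometric sorting from the lungs of male C57Bl/6 mice aged 10 weeks. The animals formed a layout of 2 drinking-water treatments by 2 instillates. Metformin, a biguanide drug used in type 2 diabetes, was given in the drinking water at 100 mg/kg/day from 24 h before instillation, and other animals received vehicle. The instillate was 10 µg of a standard urban particulate matter (PM) or phosphate-buffered saline (PBS), and cells were collected 24 h later. The groups were vehicle with PBS (n = 4), metformin with PBS (n = 3), vehicle with PM (n = 3) and metformin with PM (n = 3). Counts assigned to genes, in megacounts (M), totalled 6.12 ± 0.373 M per library with vehicle and PBS (SD; range 5.567 to 6.362), 6.26 ± 0.148 M with metformin and PBS (6.17 to 6.434). They were 6.61 ± 0.467 M with vehicle and PM (6.182 to 7.107) and 7.50 ± 0.863 M with metformin and PM (6.515 to 8.101). Libraries are named below by group and by the number in their titles.

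Replicates of a group correlated at r = 0.98732 to 0.99239 across genes on the log2 counts per M (CPM) scale, and no pair of replicates agreed within sampling noise. On the first principal component, with 26.8% of the variance, PBS libraries lay at −18.14 to −8.1 and PM libraries at 7.33 to 20.52. On the second, with 16.7%, metformin libraries lay at −13.64 to −8.9 and vehicle libraries at 1.83 to 20.19. The labels name no sequencing batch, and the library numbers in the titles rise in order through the groups, so processing order and group could not be told apart. Some numbers in that series are missing, all outside the vehicle PBS group, and the reason is not known here.

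**Figure D1:**
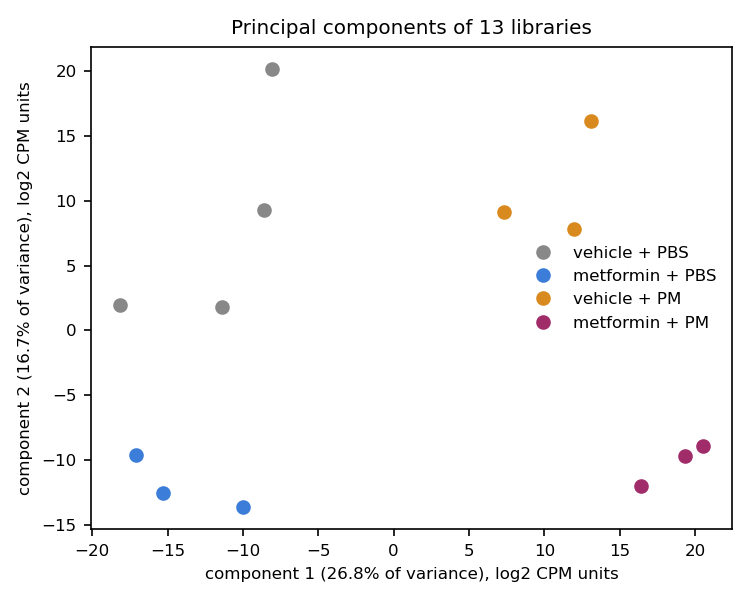
Each point is 1 of the 13 libraries, placed by its score on the first and second principal components of log2 CPM, and colours mark the 4 groups. PM libraries lie at 7.33 or above on component 1, and metformin libraries at −8.9 or below on component 2.

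Of 11906 genes tested with edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 309 were higher and 269 lower with PM than with PBS in animals on vehicle, and 855 were higher and 667 lower in animals on metformin. Metformin was followed by 135 higher and 230 lower genes in PBS animals, and by 486 higher and 334 lower genes in PM animals. The PM effect differed between the drinking-water arms for 171 genes, 106 with a more positive and 65 with a more negative effect under metformin. Lists of genes fixed before the data were examined were tested with camera, and each list's members are counted over all genes and adjusted over the list alone. Where few members of a list passed, some or all are named where reported, and those outside the rule for named genes were picked after their values were seen. The largest rises and falls named in the 4 simple comparisons had no overlap in CPM between the libraries of the groups compared.

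**Figure D2:**
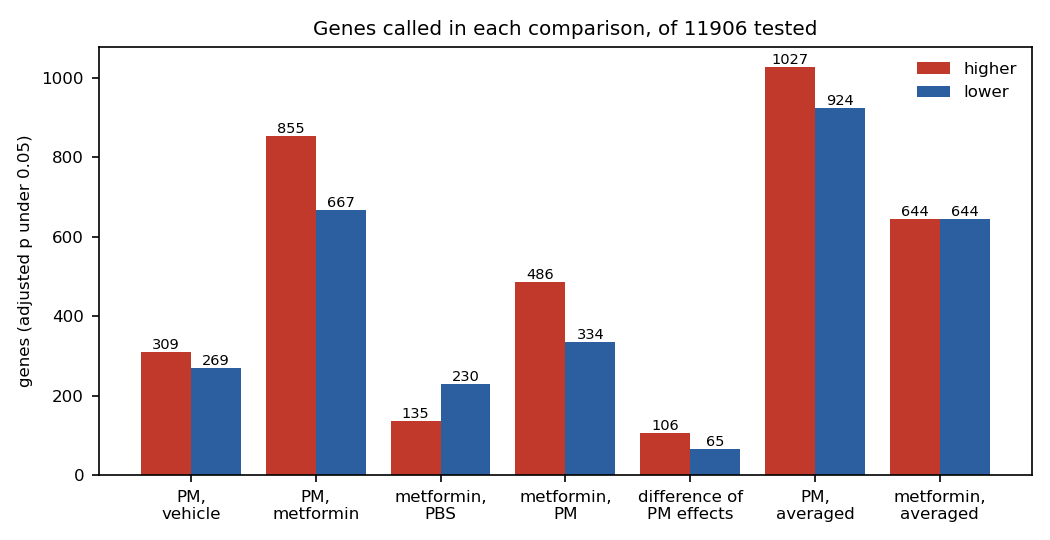
Bars give the number of genes, of 11906 tested, with an adjusted p under 0.05 in each of the 7 comparisons, red for higher and blue for lower. The PM effect with metformin holds 855 higher and 667 lower genes, against 309 and 269 with vehicle.

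The comparison of PM with PBS in animals on vehicle asks what followed the particles by themselves in the sorted cells. Markers of monocytes and monocyte-derived macrophages, Mmp14 among them, rose as well, and a change in the mix of cells sorted was not tested. PM was followed by higher RNA of cytokines and chemokines, of cholesterol synthesis enzymes and of antioxidant genes. Mmp14, a membrane-bound metalloproteinase (ENSMUSG00000000957; chromosome 14, 54431604 to 54441258), rose from 0.439 ± 0.369 CPM (SD, n = 4) to 12.3 ± 5.2 CPM (n = 3), a log2 fold change of 4.71 ± 0.40 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.485e-07). Ass1, an enzyme of arginine synthesis (ENSMUSG00000076441; chromosome 2, 31470207 to 31520672), rose by 4.34 ± 0.30. The receptor gene Met rose by 3.86 ± 0.36, the activin subunit gene Inhba by 3.05 ± 0.40, and the peptidase gene Anpep by 2.59 ± 0.15. Il6, which encodes interleukin 6 (ENSMUSG00000025746; chromosome 5, 30013161 to 30019968), went from 15.4 ± 8.43 to 56.3 ± 10.9 CPM (log2 fold change 1.86 ± 0.26; edgeR quasi-likelihood adjusted p = 0.000142). Its 3 PM libraries (44 to 64.7 CPM) lay above all 4 PBS libraries (8.40 to 27.1 CPM). Tnf, encoding tumour necrosis factor (ENSMUSG00000024401; chromosome 17, 35199381 to 35202007), rose by 1.31 ± 0.28 and the neutrophil-attracting chemokine genes Cxcl3 (ENSMUSG00000029379; chromosome 5, 90786103 to 90788086) and Cxcl1 by 2.75 ± 0.25 and 1.40 ± 0.18. Among the largest falls were the nuclear receptor gene Esrrg (−1.35 ± 0.20), the membrane protein gene Mfsd6 (−1.24 ± 0.12), the glutamate transporter gene Slc1a3 (−1.22 ± 0.23) and Pdk4, which encodes a kinase that restrains pyruvate oxidation (−0.95 ± 0.17). Of a panel of response genes set in advance, Cxcl2 rose by 0.996 ± 0.163. Siglecf, a surface lectin of alveolar macrophages, fell (−0.20 ± 0.05; not called without vehicle PBS 4, −0.186, or without vehicle PM 1 or 3, −0.201 each), while Srxn1, Tiparp and Pparg were not called. In the set of genes called, 85 rose and 12 fell more than 2-fold. Leaving out vehicle PM 2 lowered the count from 578 to 359 genes.

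Inflammatory signalling genes rose as groups with PM. Monocyte and monocyte-derived macrophage markers rose in the same libraries (list mean 0.597 above vehicle PBS, against 0.717 for cytokines and chemokines), and a link was not tested. Of 24 cytokines and chemokines, 11 rose, among them Il1b (1.29 ± 0.17), Il1a (1.24 ± 0.20) and the chemokine gene Ccl9 (1.17 ± 0.14), and 16 rose when adjusted over the list alone. The 1 member that fell was Il18 (−0.20 ± 0.05), whose fall was not called without vehicle PBS 2 or without any 1 of the 3 vehicle PM libraries. Adjusted over the list alone 2 fell. The list as a whole was higher (camera adjusted p = 1.21e-08), with an adjusted p = 0.0959 with an estimated correlation. Ccl2, a monocyte chemoattractant (ENSMUSG00000035385; chromosome 11, 82035571 to 82037453), was not called (−0.36 ± 0.18; edgeR adjusted p = 0.351). Of 24 feedback targets of the transcription factor NF-kB, 17 rose, including the mitochondrial superoxide dismutase gene Sod2 (0.86 ± 0.08), the itaconate synthase gene Acod1 (3.83 ± 0.54) and the ubiquitin-editing enzyme gene Tnfaip3 (1.002 ± 0.142). Adjusted over the list alone 19 of them rose (camera adjusted p = 1.57e-18, adjusted p = 0.0959 with an estimated correlation). Of 23 immediate early genes, which are induced within minutes of many stimuli, 9 rose, led by Socs3 (1.91 ± 0.17) and Egr1 (1.43 ± 0.21). Atf3 fell (−0.26), but not without any 1 library other than vehicle PBS 4. Adjusted over the list alone 11 rose and 2 fell (camera adjusted p = 7.25e-06, adjusted p = 0.369 with an estimated correlation). None of 27 interferon-stimulated genes was called by edgeR, by DESeq2 or at an unadjusted p under 0.05 (0 each, and 0 adjusted over the list alone; camera adjusted p = 0.241).

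Cholesterol synthesis was the list with the lowest p in this comparison. Of 24 members 17 rose, and 20 adjusted over the list alone, and the median log2 fold change was 0.692 (camera adjusted p = 5.99e-24, adjusted p = 0.0959 with an estimated correlation). The enzyme genes Cyp51 and Hmgcs1 rose by 0.98 ± 0.10 and 0.67 ± 0.06. Of 30 targets of the oxidative stress factor NRF2, 11 rose and 15 rose adjusted over the list alone (camera adjusted p = 1.15e-10, adjusted p = 0.23 with an estimated correlation). The cystine transporter gene Slc7a11 (ENSMUSG00000027737; chromosome 3, 49892526 to 50443614) rose by 2.62 ± 0.21, the quinone reductase gene Nqo1 by 1.61 ± 0.29 and the haem oxygenase gene Hmox1 by 1.27 ± 0.22. Without vehicle PM 2, 7 NRF2 targets rose, the value of Hmox1 was 0.735, and the thioredoxin reductase gene Txnrd1 (0.29 ± 0.07) was no longer called at 0.241. Of 28 targets of the integrated stress response, 5 rose (Slc7a11, Aars, Asns, Mthfd2 and Ppp1r15a) and 2 fell (Sesn2 and Atf3), or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00246, adjusted p = 0.0959 with an estimated correlation). Without vehicle PM 1, 3 rose, and no fall was called without vehicle PBS 2, vehicle PM 1 or vehicle PM 2 (1 without vehicle PBS 1, vehicle PBS 3 or vehicle PM 3). Of 16 metal-responsive genes the transporter genes Slc11a1 (2.22 ± 0.24) and Slc11a2, the transferrin receptor gene Tfrc (0.92 ± 0.12) and the ferritin gene Fth1 rose. The stress-responsive gene Ndrg1 (−0.92 ± 0.22; −0.655 and not called without vehicle PM 2) and the zinc exporter gene Slc30a1 fell. There was 1 fall without vehicle PBS 1 or any 1 vehicle PM library (4 rises and 2 falls adjusted over the list alone; camera adjusted p = 0.0835). The metallothionein genes Mt1 (0.06 ± 0.07) and Mt2 (0.09 ± 0.11) were not called. Of 7 targets of the aryl hydrocarbon receptor, a sensor of polycyclic aromatic compounds, Cd93 rose (0.78 ± 0.20), but not without vehicle PBS 3 (0.689), vehicle PBS 4 (0.721) or vehicle PM 2 (0.442), and with DESeq2 no target was called (0.787 for Cd93). Adjusted over the list alone 1 of the targets rose and 1 fell (camera adjusted p = 0.704). The receptor's classic target Cyp1a1 was too low to be tested, with 2, 0, 0 and 3 counts summed over the libraries of vehicle PBS, metformin PBS, vehicle PM and metformin PM, and so were Cyp1b1, Ahrr and Ppargc1a.

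Small shifts of whole lists accounted for most other list calls. Cell division genes had a median of 0.176 over 45 members with 1 called rise (0 adjusted over the list alone; camera adjusted p = 7.25e-06, adjusted p = 0.48 with an estimated correlation). That gene was Bub1b (0.29 ± 0.08), and no member was called when any 1 library other than vehicle PBS 1 was left out, while 12 rose without that library, and the list was not called without vehicle PBS 4 (adjusted p = 0.0535). The ribosomal protein list rose (median 0.135; camera adjusted p = 2.09e-15, adjusted p = 0.369 with an estimated correlation), with 10 of 74 members higher and 33 adjusted over the list alone. The count was 0 without vehicle PM 2, 2 without vehicle PBS 4, 3 without vehicle PBS 2 and 5 without vehicle PM 3. No member was called by edgeR, alone or adjusted over the list alone, among the subunits of respiratory complex I (36 genes, median 0.084), of complexes II to V (39 genes, 0.085) and of those encoded in mitochondria (12 genes, 0.126). At an unadjusted p under 0.05 they had 5, 9 and 4 rises, and with DESeq2 0, 0 and 1. Their camera adjusted p values were 0.00226, 0.000121 and 0.0301, with adjusted p = 0.43, 0.43 and 0.366 with an estimated correlation. Complex I was not called without vehicle PM 2 (0.116), and the mitochondrially encoded genes not without vehicle PBS 4 (0.0772) or vehicle PM 3 (0.107). Endoplasmic reticulum stress genes were shifted upward (24 genes; camera adjusted p = 0.00359, adjusted p = 0.484 with an estimated correlation) with no member called by edgeR or DESeq2, 0 adjusted over the list alone and 4 higher unadjusted. Heat shock genes (17 genes, median 0.108) likewise had 0 called by edgeR or DESeq2, 0 adjusted over the list alone and 2 unadjusted (camera adjusted p = 0.0314, adjusted p = 0.598 with an estimated correlation). That call was lost without vehicle PBS 1 (0.288), vehicle PBS 4 (0.0622), vehicle PM 1 (0.0968), vehicle PM 2 (0.0671) or vehicle PM 3 (0.067).

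Of 36 lysosome and autophagy genes 7 rose, among them the protease gene Ctsk (0.75 ± 0.08), and 7 adjusted over the list alone (camera adjusted p = 0.000851, adjusted p = 0.43 with an estimated correlation). Without vehicle PBS 2, 3 or 4 the count was 4, and without vehicle PM 2 it was 1 and the list was not called (0.0781). Of 22 glycolysis genes Eno1 (0.46 ± 0.06), the glucose transporter gene Slc2a1 (0.61 ± 0.11) and Pgam1 rose, and 5 rose adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.377 with an estimated correlation). That call was lost without vehicle PBS 3 (0.075) or vehicle PM 2 (0.14). Of 31 fatty acid oxidation and PPAR targets the lipid chaperone genes Fabp5 (0.54 ± 0.09) and Fabp4 rose. Acot1 (−0.64 ± 0.08), Pdk4 and Acot2 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.0835; 5 fell without vehicle PBS 3). Of 16 fatty acid synthesis genes Me1 rose and Dgat1 fell (−0.56 ± 0.13; not without vehicle PM 1, −0.525, vehicle PM 2, −0.497, or vehicle PBS 4, −0.479), or 2 and 2 adjusted over the list alone (camera adjusted p = 0.301). Of 25 mitochondrial biogenesis genes the uncoupling protein gene Ucp2 fell (−0.25 ± 0.05; 1 adjusted over the list alone; camera adjusted p = 0.674, lower, with a median of −0.018 and a mean of 0.001). Of 21 genes of the AMPK and mTOR pathways Sesn2 fell (−0.34 ± 0.08; not without vehicle PBS 2, vehicle PM 1 or vehicle PM 2), or 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.598). Of 26 genes of store-operated calcium entry Orai3 and Saraf fell (3 adjusted over the list alone; camera adjusted p = 0.329). There was 1 fall with DESeq2 or without vehicle PBS 1 or 2 and 0 without vehicle PM 1 or 3. The core members Stim1 and Orai1 were not called (−0.19 ± 0.06 and 0.13). Of 18 coagulation and fibrinolysis genes the factor X gene F10 (0.57 ± 0.07) and the von Willebrand factor gene Vwf (0.39 ± 0.07) rose, and 5 rose adjusted over the list alone (camera adjusted p = 0.0502). The tissue factor gene F3 was too low to be tested.

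Cell type markers moved in several directions with PM. Of 37 alveolar macrophage markers 9 rose, such as the carbonic anhydrase gene Car4 (1.11 ± 0.08). Another 7 fell, such as the ribonuclease genes Ear1 (−0.56 ± 0.06) and Ear2 (−0.35 ± 0.05), or 12 and 11 adjusted over the list alone (camera adjusted p = 0.764). Of 17 markers of monocytes and monocyte-derived macrophages 7 rose, including Mmp14, Mmp12 (1.64 ± 0.25) and the integrin gene Itgam (1.36 ± 0.17), and 8 adjusted over the list alone (camera adjusted p = 0.000314, adjusted p = 0.0959 with an estimated correlation). Of 7 neutrophil markers Wfdc21 (0.78 ± 0.07) and the haptoglobin gene Hp (2.16 ± 0.25) rose, or 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.566, higher, with a median of −0.109 and a mean of 0.225). Of 12 genes of MHC class II antigen presentation Cd86 and H2-DMa fell, and 3 adjusted over the list alone (camera adjusted p = 0.00574, adjusted p = 0.366 with an estimated correlation). Neither fall was called without vehicle PM 1, only 1 without vehicle PBS 1, 2 or 4 or vehicle PM 2 or 3, and the list was not called without vehicle PM 2 (0.0558). Of 3 lymphocyte markers tested the immunoglobulin genes Igkc (2.53 ± 0.65) and Jchain (2.70 ± 0.77) rose, and 2 rose and 1 fell adjusted over the list alone. With DESeq2 1 rose and 1 fell, and Jchain was not called (2.811). No rise was called without vehicle PBS 1, vehicle PM 1 or vehicle PM 2, and only 1 without vehicle PBS 2, 3 or 4. The platelet factor gene Pf4, the 1 member tested of the erythroid and platelet list, rose (2.13 ± 0.36; 1 adjusted over the list alone). Pf4 is also on the list of monocyte and monocyte-derived macrophage markers, so its rise does not single out platelets. Siglece, the 1 member tested of the eosinophil and basophil list, was not called by edgeR or DESeq2 or at an unadjusted p under 0.05. With 1 member tested, that list cannot show whether such cells were present. No member was called by edgeR or DESeq2, and none adjusted over the list alone, among dendritic cell markers (7 tested, 3 lower unadjusted, camera adjusted p = 0.0893) and lung epithelium markers (18 tested, 3 higher and 2 lower unadjusted, 0.603). Among 23 endothelium and fibroblast markers 1 rose, Vwf (1 adjusted over the list alone, 0.603).

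The same comparison in animals on metformin asks what PM did to cells already exposed to the drug. PM was again followed by more RNA of Mmp14, Ass1 and chemokines, together with cell division, coagulation and endothelial genes. Mmp14 rose by 4.42 ± 0.40 to 12.9 ± 0.807 CPM, Ass1 by 3.56 ± 0.33 and Inhba by 4.04 ± 0.41 (edgeR quasi-likelihood adjusted p = 6.252e-07, 6.524e-07 and 1.763e-06). The chemokine gene Ccl9 (ENSMUSG00000019122; chromosome 11, 83572919 to 83578636) rose from 43.2 ± 8.85 to 301.5 ± 46.5 CPM, a log2 fold change of 2.81 ± 0.16. Abtb2 rose by 3.97 ± 0.33, the T cell attracting chemokine gene Ccl17 by 3.16 ± 0.39 and Hp by 2.55 ± 0.29. Rhob, encoding a small GTPase (ENSMUSG00000054364; chromosome 12, 8497763 to 8499985), fell by 1.28 ± 0.10, from 450.3 ± 62.6 to 185.0 ± 19.1 CPM. Apoe, encoding apolipoprotein E (ENSMUSG00000002985; chromosome 7, 19696109 to 19699166), fell by 1.10 ± 0.14. The 1522 calls fell to 895 without metformin PBS 3, 964 without metformin PBS 4 and 884 without metformin PM 3.

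Il6 rose by 1.43 ± 0.28, Tnf by 1.33 ± 0.31 and Ccl2 by 1.25 ± 0.17, and Il1a, Il1b, Cxcl1, Cxcl2, Txnrd1 and Pparg rose as well. Siglecf fell (−0.22 ± 0.05; −0.18 and not called without metformin PM 3), and Srxn1, Tiparp, Stim1 and Orai1 were not called. Of 24 cytokines and chemokines 15 rose, and 19 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.71e-11, adjusted p = 0.088 with an estimated correlation). Of the 24 NF-kB targets 15 rose, among them the urokinase receptor gene Plaur (0.81 ± 0.08), Sod2 (0.69 ± 0.08) and Ier3 (1.47 ± 0.19). Tnfaip2 fell, and 20 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.34e-11, adjusted p = 0.088 with an estimated correlation). Of the 18 coagulation and fibrinolysis genes 7 rose and Pros1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00317, adjusted p = 0.088 with an estimated correlation). Risers were Plaur, F10 (0.50 ± 0.07) and Thbs1, which encodes the platelet-binding protein thrombospondin 1 (ENSMUSG00000040152; chromosome 2, 118111876 to 118127133) and rose by 2.33 ± 0.44. The fall of Pros1 was not called without metformin PBS 3 or metformin PM 3. Of the 30 NRF2 targets 6 rose, including Slc7a11 (1.06 ± 0.20) and Esd (0.61 ± 0.10), and Ephx1 fell, but not without metformin PM 3. The counts were the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.304). Nqo1 (0.39 ± 0.30), Hmox1 (0.19 ± 0.23) and Gclm (0.08 ± 0.08) were not called. Of 16 metal-responsive genes 6 rose, Mt2 (0.92 ± 0.12; ENSMUSG00000031762; chromosome 8, 94172618 to 94173567), Mt1 (0.47 ± 0.08) and Ndrg1 (1.15 ± 0.22) among them, and 6 adjusted over the list alone (camera adjusted p = 0.00464, adjusted p = 0.088 with an estimated correlation).

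Cell division genes rose in 36 of 45 cases, and 40 adjusted over the list alone, with a median of 0.666 (camera adjusted p = 1.24e-18, adjusted p = 0.267 with an estimated correlation), and 23 rose without metformin PM 3. The proliferation marker Mki67 (ENSMUSG00000031004; chromosome 7, 135689788 to 135716379) rose by 0.71 ± 0.13 and the topoisomerase gene Top2a by 0.77 ± 0.13. These rises started from the metformin PBS group, whose Mki67 level of 133.2 ± 7.75 CPM lay below the 225.6 ± 50.3 CPM of vehicle PBS, and ended at 217.3 ± 25.2 CPM. Of the 24 cholesterol genes 9 rose, among them Insig1 (0.57 ± 0.08), and 12 adjusted over the list alone (camera adjusted p = 4.27e-06, adjusted p = 0.345 with an estimated correlation); 14 rose without metformin PM 1. Endoplasmic reticulum stress genes rose in 15 of 24 cases, with Creld2 (0.65 ± 0.11) and Xbp1 (0.35 ± 0.07), and in 19 adjusted over the list alone (camera adjusted p = 3.42e-07, adjusted p = 0.341 with an estimated correlation). That count was 3 without metformin PBS 3 or metformin PM 3, 7 without metformin PBS 4, 9 without metformin PM 1 and 8 without metformin PM 4. Hspa4l (0.49 ± 0.08), Chordc1 and Stip1 rose of 17 heat shock genes, and 6 adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.529 with an estimated correlation). The count was 1 without metformin PBS 3 or metformin PM 3 and 7 without metformin PBS 1, with no call of the list without metformin PBS 3 (0.128). The immediate early list held rises of Socs3 (1.83 ± 0.18) and Egr2 and 5 falls, Klf4 (−0.42 ± 0.07), Klf2, Btg2, Jun and Atf3, or 3 and 6 adjusted over the list alone. As a whole it was not called (camera adjusted p = 0.479, lower, with a median of −0.032 and a mean of 0.065; 4 rose without metformin PBS 1).

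Genes of complexes II to V rose in 7 of 39 cases, and 8 adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.413 with an estimated correlation). There were 0 rises without metformin PBS 3, metformin PBS 4 or metformin PM 3, 3 without metformin PM 1, 2 without metformin PM 4 and 13 without metformin PBS 1, and 3 with DESeq2. Mitochondrially encoded subunits such as mt-Cytb (0.27 ± 0.05) rose in 7 of 12 cases, 8 adjusted over the list alone (camera adjusted p = 0.00401, adjusted p = 0.252 with an estimated correlation), and in 4 without metformin PBS 1 or metformin PM 3. Lysosome genes rose in 9 of 36 cases and Tfeb, a regulator of lysosome biogenesis, fell (−0.62 ± 0.07). The counts were 11 and 1 adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.529 with an estimated correlation), with 4 rises without metformin PBS 3 and 5 without metformin PM 4. Ribosomal protein genes shifted by a median of 0.115 with 8 of 74 called, 4 adjusted over the list alone (camera adjusted p = 5.52e-07, adjusted p = 0.558 with an estimated correlation). Their count was 0 without metformin PBS 3 or metformin PM 3, 1 without metformin PBS 4 or metformin PM 4, 3 without metformin PM 1 and 20 without metformin PBS 1.

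Markers of other cells rose with PM in this arm beside these groups. Of 23 endothelium and fibroblast markers 11 rose, and 16 adjusted over the list alone, with a median of 1.028 (camera adjusted p = 3.42e-07, adjusted p = 0.309 with an estimated correlation). Sparcl1, a secreted matrix protein of vessels and stroma (ENSMUSG00000029309; chromosome 5, 104079111 to 104114088), rose by 1.70 ± 0.29 and the endothelial adhesion gene Pecam1 by 1.13 ± 0.25. The count was 7 without metformin PBS 1 or 3, 6 without metformin PM 3 and 5 without metformin PBS 4 or metformin PM 4. Of 18 lung epithelium markers the surfactant genes Sftpa1 (1.51 ± 0.33), Sftpc (1.23 ± 0.27) and Sftpb with Lamp3 and Slc34a2 rose, and Tppp3 and Epcam fell, also adjusted over the list alone (5 and 2; camera adjusted p = 0.0863). Rises numbered 3 without metformin PBS 3 and 2 without metformin PBS 4 or metformin PM 4, and falls 0 without metformin PM 3 and 1 without metformin PBS 3 or metformin PM 4. Monocyte and macrophage markers rose in 8 of 17 cases, with Mmp12 at 2.39 ± 0.28 and Itgam at 1.67 ± 0.20. Apoe fell, and the counts were 9 and 2 adjusted over the list alone (camera adjusted p = 0.000478, adjusted p = 0.088 with an estimated correlation). Without metformin PBS 3 the rises numbered 5, and 2 fell without metformin PBS 1. Of 7 neutrophil markers 4 rose, Wfdc21, Hp, Trem1 (0.41 ± 0.07) and Mmp8, also adjusted over the list alone (4; camera adjusted p = 0.0037, adjusted p = 0.088 with an estimated correlation). Alveolar macrophage markers went both ways, 12 up and 9 down, or 13 and 11 adjusted over the list alone (camera adjusted p = 0.928, with a median of −0.017 and a mean of 0.049). The scavenger receptor gene Marco (ENSMUSG00000026390; chromosome 1, 120474538 to 120505024) rose by 1.44 ± 0.18.

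Metformin was compared with vehicle in PBS animals to ask what the drug did to unexposed cells. It was followed by more RNA of heat shock proteins and less of cell division genes. Hspa1b (ENSMUSG00000090877; chromosome 17, 34956436 to 34959238) and Hspa1a (ENSMUSG00000091971; chromosome 17, 34969190 to 34972156), which encode inducible HSP70 chaperones, rose by 2.70 ± 0.38 and 2.24 ± 0.31 (edgeR quasi-likelihood adjusted p = 0.00199 for each). They are near-identical copies, so the division of reads between them is uncertain. Hspa1b went from 6.21 ± 3.03 to 40.4 ± 22.5 CPM, and all 3 metformin libraries (14.7 to 56.2) lay above the vehicle libraries (2.22 to 9.4). The co-chaperone genes Hsph1 and Dnaja1 rose by 1.07 ± 0.18 and 0.96 ± 0.14, Apoe by 1.07 ± 0.13 and Slc7a11 by 1.38 ± 0.24. The mitotic motor gene Kif14 fell by 1.24 ± 0.19, Cep55 by 1.16 ± 0.19, Marco by 1.11 ± 0.17 and Ccl9 by 1.11 ± 0.16. Neither Il6 (0.21 ± 0.31; edgeR adjusted p = 0.797) nor Tnf (−0.35 ± 0.29; 0.583) was called, and without metformin PBS 1 the value of Il6 was −0.258; Slc7a11 was the 1 gene of the preset panel that was called. The 365 calls were 151 without vehicle PBS 1, 215 without vehicle PBS 2, 121 without metformin PBS 4 and 200 with only these 2 groups in the model, against 813 with no filter on low counts. Higher genes made up 36.99% of the 365 calls but 49.69% of the 813, so the excess of falls was absent without the filter.

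Of 45 cell division genes 37 fell, and 42 adjusted over the list alone, with a median of −0.751 (camera adjusted p = 2.41e-32, adjusted p = 0.75 with an estimated correlation). Mki67 fell by 0.76 ± 0.12 and the spindle gene Tpx2 by 0.94 ± 0.13, and 18 members fell without metformin PBS 4. Heat shock genes rose in 9 of 17 cases, and 12 adjusted over the list alone (camera adjusted p = 9.3e-11, adjusted p = 0.75 with an estimated correlation), with 5 without metformin PBS 4. Of 24 cholesterol genes 3 rose, Insig1 (0.38 ± 0.08) and Mvd among them, and 7 adjusted over the list alone (camera adjusted p = 0.00419, adjusted p = 0.75 with an estimated correlation); Insig1 was not called without metformin PBS 4 (0.343). Among MHC class II genes Cd74, H2-Ab1, H2-Aa (not called with DESeq2, 0.713) and H2-DMa rose, 7 of 12 adjusted over the list alone (camera adjusted p = 0.00419, adjusted p = 0.75 with an estimated correlation). No rise in that list was called without vehicle PBS 1, vehicle PBS 2, metformin PBS 3 or metformin PBS 4, 2 were called without vehicle PBS 3 and 6 without metformin PBS 1. Without metformin PBS 3 the list was not called (0.0519). Of the NRF2 targets Slc7a11 and Me1 rose, 3 of 30 adjusted over the list alone (camera adjusted p = 0.00419, adjusted p = 0.75 with an estimated correlation), and Slc7a11 alone without vehicle PBS 1, vehicle PBS 3 or metformin PBS 4. Endoplasmic reticulum stress genes Herpud1 (0.71 ± 0.13), Syvn1 and Hspa5 rose, 8 of 24 adjusted over the list alone (camera adjusted p = 0.0133, adjusted p = 0.75 with an estimated correlation). The count was 1 without vehicle PBS 1, metformin PBS 1 or metformin PBS 4 and 6 without metformin PBS 3, and the list was not called without metformin PBS 1 (0.658). Of 31 fatty acid oxidation and PPAR targets Acot1 (−0.41 ± 0.07), the lipase gene Lpl (−0.31 ± 0.06) and Cd36 fell, or 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0227, adjusted p = 0.75 with an estimated correlation). That list was not called without vehicle PBS 1 (0.0913) or metformin PBS 3 (0.134), and Cd36 not without metformin PBS 3 (−0.3) or metformin PBS 4 (−0.34).

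Metformin is known to act on respiratory complex I and on AMPK. The counts here give only the RNA of their genes, and the activity of complex I or AMPK was not measured. No member of the complex I list (36 genes; camera adjusted p = 0.965), of complexes II to V (39; 0.555) or of the AMPK and mTOR list (21; 0.391) was called by edgeR or DESeq2 or adjusted over the list alone in PBS animals. At an unadjusted p under 0.05 there were 1 lower complex I gene, 0 genes of complexes II to V and 3 higher AMPK and mTOR genes. Mitochondrially encoded subunits shifted downward (camera adjusted p = 0.0451, adjusted p = 0.75 with an estimated correlation), with mt-Nd4 called (2 of 12 adjusted over the list alone). The list was not called without vehicle PBS 1 (0.053), vehicle PBS 2 (0.12), vehicle PBS 3 (0.0961), metformin PBS 1 (0.0753) or metformin PBS 4 (0.0781). For mt-Nd4 the call was kept only when vehicle PBS 4 was the library left out. Immediate early genes shifted upward (median 0.108; camera adjusted p = 0.0389, adjusted p = 0.75 with an estimated correlation) with 0 of 23 called by edgeR, 0 adjusted over the list alone, 5 unadjusted and 1 by DESeq2. Leaving out vehicle PBS 3 gave 7 rises, and the list was not called without vehicle PBS 1 (0.155), vehicle PBS 2 (0.12), vehicle PBS 4 (0.166) or metformin PBS 1 (0.575). Coagulation genes had 0 of 18 called by edgeR, 1 rise adjusted over the list alone, 3 rises and 1 fall unadjusted and 1 rise by DESeq2 (camera adjusted p = 0.965). Of 37 alveolar macrophage markers 3 rose (Mertk, Bhlhe40 and Fcgr1) and 5 fell (Marco, Il1rn, Lpl, Slc39a2 and Serpinb1a), or 4 and 6 adjusted over the list alone. Rises numbered 0 without vehicle PBS 1 and 1 without vehicle PBS 2, metformin PBS 1 or metformin PBS 4, and falls 3 without metformin PBS 3 and 2 without metformin PBS 4. No endothelium or fibroblast marker was called by edgeR or DESeq2 or adjusted over the list alone (3 lower unadjusted; camera adjusted p = 0.385).

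**Figure D3:**
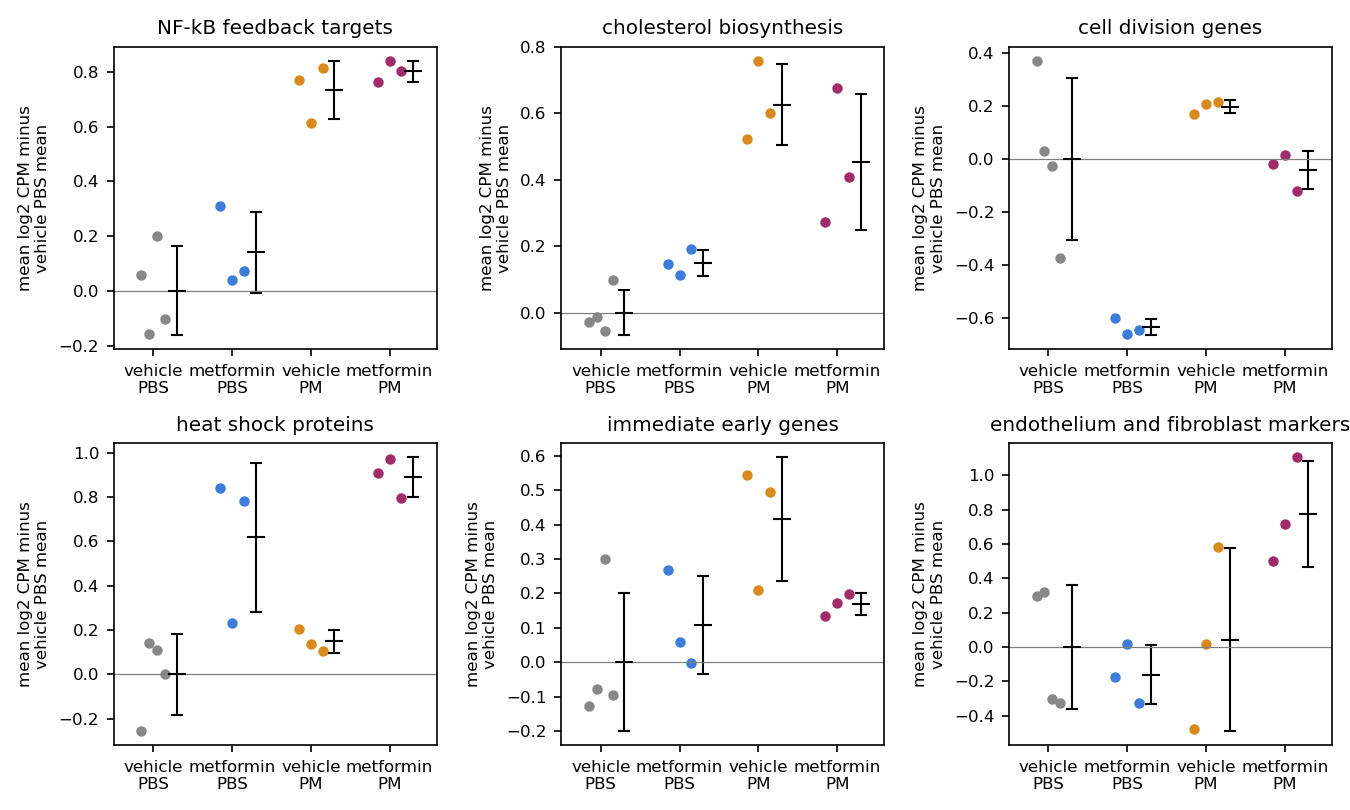
Each point is 1 library's mean log2 CPM over the tested members of a list, minus the mean of the vehicle PBS group, with the group mean and SD beside the points (n = 4, 3, 3 and 3). Cell division genes lie at −0.657 to −0.597 in the metformin PBS libraries, against −0.374 to 0.37 with vehicle and PBS, and heat shock genes at 0.23 to 0.84 with metformin and PBS.

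In PM animals, metformin was compared with vehicle to ask how the drug altered cells that had met the particles. Metformin was again followed by more RNA of heat shock proteins, and PM-exposed cells on metformin also held more RNA of the transcription factor Crem and of the chemokine Ccl2. Hspa1b rose by 2.55 ± 0.37, from 8.63 ± 2.57 to 50.8 ± 10.8 CPM, and Hspa1a by 1.79 ± 0.32 (edgeR quasi-likelihood adjusted p = 0.000252 and 0.00146). Crem, a cyclic AMP responsive transcription factor (ENSMUSG00000063889; chromosome 18, 3266048 to 3337748), rose by 1.85 ± 0.21 and the MAP kinase phosphatase gene Dusp16 by 1.61 ± 0.15. Ccl2 rose by 1.32 ± 0.17, from 5.80 ± 1.18 to 14.5 ± 1.31 CPM (adjusted p = 9.43e-05). Thbs1 rose by 2.04 ± 0.42 with edgeR but was not called with DESeq2 (2.027). The dendritic cell factor gene Batf3 fell by 1.45 ± 0.25, the alveolar macrophage factor gene Bhlhe41 by 0.98 ± 0.11 and the stress cytokine gene Gdf15 by 0.94 ± 0.16. The RNA of Il6 (−0.22 ± 0.24; edgeR adjusted p = 0.67), Tnf (−0.33 ± 0.30; 0.598) and Slc7a11 (−0.18; 0.638) was not called as different. Beside Ccl2 and Mt2, the calcium channel gene Orai1 was the 1 other panel gene called (0.34 ± 0.09), and its call was lost without any 1 of the 6 libraries (0.289 to 0.359). The 820 calls were 419 without vehicle PM 2 and 431 without metformin PM 1.

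Heat shock genes rose in 12 of 17 cases, and 14 adjusted over the list alone (camera adjusted p = 2.2e-12, adjusted p = 0.626 with an estimated correlation), with Hsph1 at 1.52 ± 0.19 and Hspa4l at 0.68 ± 0.08. Endoplasmic reticulum stress genes rose in 11 of 24 cases, and 15 adjusted over the list alone, such as Xbp1 (0.48 ± 0.07) and Herpud1 (0.80 ± 0.13; camera adjusted p = 1.04e-07, adjusted p = 0.626 with an estimated correlation). Of 23 immediate early genes 7 fell, among them Dusp1 (−0.66 ± 0.12), Fos (−0.53 ± 0.11) and Btg2 (−0.51 ± 0.09). Nr4a2 rose, and 11 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00133, adjusted p = 0.694 with an estimated correlation). The rise of Nr4a2 was not called without vehicle PM 2, vehicle PM 3, metformin PM 1 or metformin PM 4. Among fatty acid synthesis genes Dgat2 (0.93 ± 0.10), Lpin1 (0.69 ± 0.09), Elovl6 (1.24 ± 0.17) and Dgat1 rose. Srebf1 (−0.39 ± 0.06) and Scd2 fell, and the counts were 5 and 3 of 16 adjusted over the list alone (camera adjusted p = 0.767, lower, with a median of −0.132 and a mean of 0.047). Plaur (0.72 ± 0.08), Thbs1 and the thrombomodulin gene Thbd (0.49 ± 0.10) rose of 18 coagulation genes, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.162). Of 16 metal-responsive genes Slc30a1 (0.96 ± 0.17), Ndrg1 (1.18 ± 0.22) and Mt2 (0.50 ± 0.11; not called without vehicle PM 3, 0.446) rose. Tfrc fell (−0.58 ± 0.12; not called without vehicle PM 2, −0.461), or 5 and 1 adjusted over the list alone.

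Cell division genes were lower as a list (median −0.215; camera adjusted p = 2.48e-06, adjusted p = 0.697 with an estimated correlation), with Bub1b (−0.39 ± 0.08), Mcm3 and Plk1 called and 3 of 45 adjusted over the list alone. Bub1b was the 1 gene called without vehicle PM 2, vehicle PM 3 or metformin PM 4. The falls numbered 1 with the replicate block, 11 with only the groups compared and 14 with no filter. Of 24 cholesterol genes 3 fell, Sqle and Lss (not called with DESeq2, −0.412) among them, and 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0212, adjusted p = 0.701 with an estimated correlation). That list was not called without vehicle PM 2 (0.197), metformin PM 1 (0.326) or metformin PM 4 (0.0756). Its falls numbered 0 without vehicle PM 2 or metformin PM 1, 1 without vehicle PM 3 or metformin PM 4 and 7 without metformin PM 3. The NRF2 list was lower (camera adjusted p = 0.0464, adjusted p = 0.703 with an estimated correlation) with the transporter gene Abcc1 called (1 adjusted over the list alone). It was not called without vehicle PM 2 (0.865) or metformin PM 3 (0.152). Without vehicle PM 2 no member was called, and 4 fell without vehicle PM 3. MHC class II genes Cd80 (0.86 ± 0.14), H2-Aa, H2-Eb1, H2-Ab1 and Cd74 rose, 6 of 12 adjusted over the list alone (camera adjusted p = 0.00011, adjusted p = 0.626 with an estimated correlation). With DESeq2 1 rise was called. Cd80 was the 1 member called without vehicle PM 1, vehicle PM 2, metformin PM 1 or metformin PM 3. Endothelium and fibroblast markers were higher beside these groups (median 0.788; camera adjusted p = 3.51e-05, adjusted p = 0.626 with an estimated correlation), with Sparcl1 (1.23 ± 0.27), Col1a1, Pecam1, Bgn and Col1a2 called and 7 higher and 1 lower adjusted over the list alone. Their number was 1 without vehicle PM 1 or 2, 3 without metformin PM 1, 2 without metformin PM 3 or 4 and 8 without vehicle PM 3, and 3 with DESeq2, which did not call Pecam1 (0.953), 2 with the replicate block and 10 with no filter. No gene of complex I or of complexes II to V was called by edgeR or DESeq2 or adjusted over the list alone, with 1 lower complex I gene and 0 others at an unadjusted p under 0.05. Of 21 AMPK and mTOR genes 1 rose and 1 fell, also 1 and 1 adjusted over the list alone and 0 and 1 with DESeq2 (camera adjusted p = 0.458), and none was called when any 1 of the 6 libraries was left out.

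**Figure D4:**
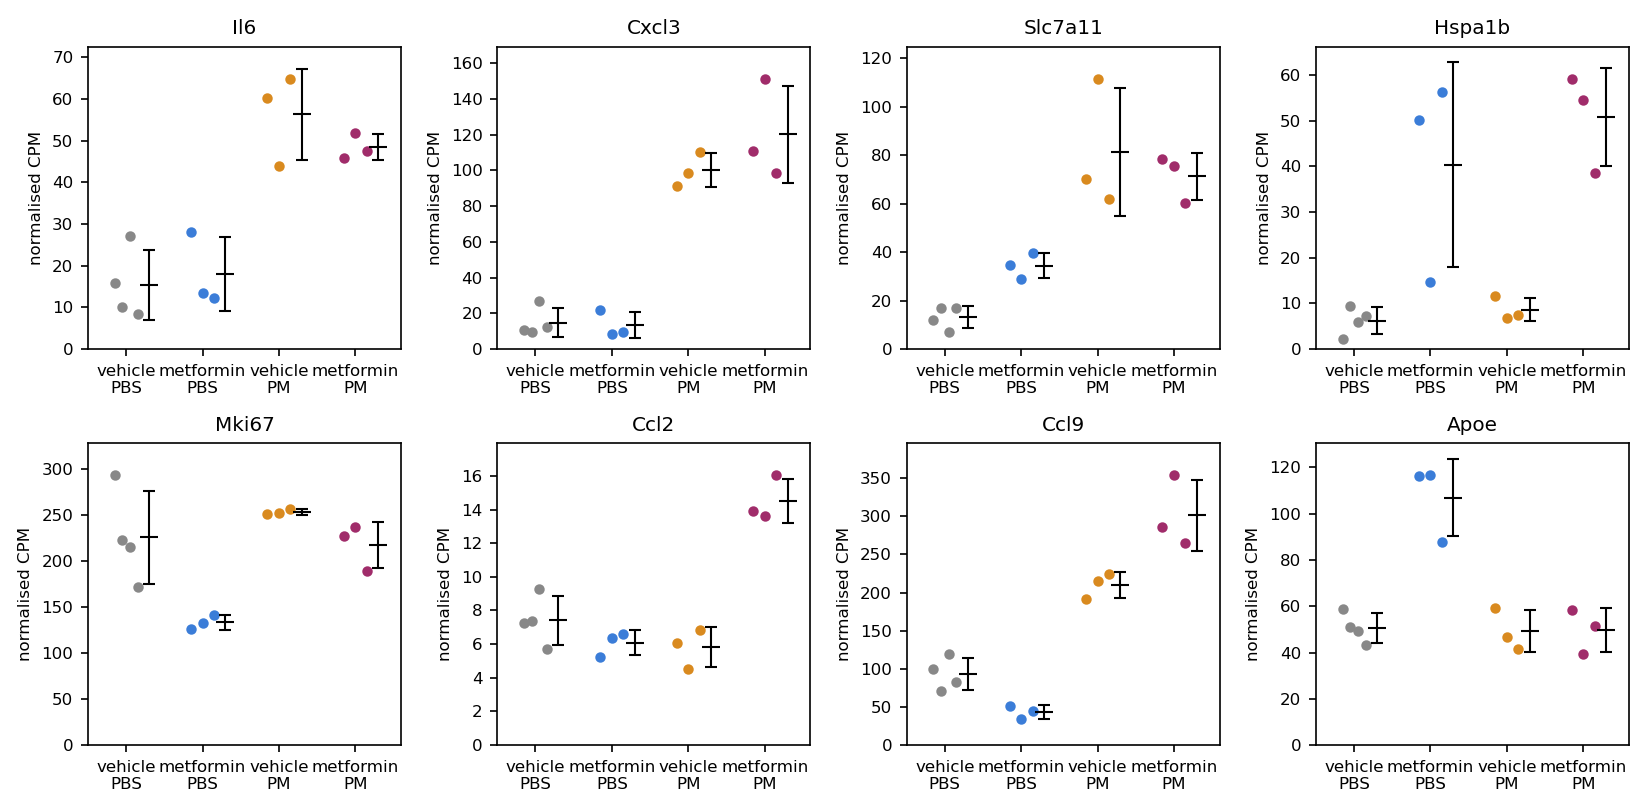
Points give the normalised CPM of 8 genes in each library, with group means and SDs (n = 4, 3, 3 and 3), on linear axes that start at 0. Ccl2 lies at 13.6 to 16.0 CPM in the metformin PM libraries, and Il6 at 45.8 to 51.9 CPM there and at 44 to 64.7 CPM with vehicle and PM.

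Whether metformin altered the response to PM is asked by the difference of the PM effects. The response of Ccl2, Ccl9, Ndrg1 and the cyclic AMP responsive gene Crem to PM was more positive with metformin, and that of Slc7a11, Apoe and Jun more negative, while the responses of Il6 and Tnf did not pass the test. Ccl2 differed by 1.60 ± 0.25 on the log2 scale (edgeR quasi-likelihood adjusted p = 0.00253), from −0.36 with vehicle to 1.25 with metformin. Ccl9 differed by 1.64 ± 0.21 and Ndrg1 (ENSMUSG00000005125; chromosome 15, 66929321 to 66969640) by 2.07 ± 0.31. The receptor genes P2ry10 (2.16 ± 0.34; ENSMUSG00000050921; chromosome X, 107088492 to 107104974) and Gpr171 (1.81 ± 0.21; ENSMUSG00000050075; chromosome 3, 59096448 to 59101821; edgeR adjusted p = 0.000275) differed as well. Crem differed by 1.72 ± 0.31 and Nr4a3, a nuclear receptor gene (ENSMUSG00000028341; chromosome 4, 48045153 to 48086447), by 1.75 ± 0.33. Slc7a11 differed by −1.56 ± 0.30, with 13.2 ± 4.63, 34.3 ± 5.22, 81.1 ± 26.4 and 71.2 ± 9.73 CPM in vehicle PBS, metformin PBS, vehicle PM and metformin PM. Apoe, at 50.7 ± 6.39, 107.0 ± 16.5, 49.2 ± 9.05 and 49.8 ± 9.67 CPM in the same order, differed by −1.06 ± 0.20. For Il6 the difference was −0.43 ± 0.39 (edgeR adjusted p = 0.751; 0.034 without metformin PBS 1) and for Tnf 0.02 ± 0.42 (0.991). Ccl2, Mt2 and Slc7a11 were the panel genes called. Of the 171 calls, 74 were not called with vehicle and rose with metformin, 43 were not called with vehicle and fell with metformin, and 25 were called with vehicle only, 13 as rises and 12 as falls. The count was 113 without metformin PBS 4 and 262 without vehicle PBS 4, against 507 with no filter on low counts.

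Of 23 immediate early genes Jun (−1.06 ± 0.20; ENSMUSG00000052684; chromosome 4, 95049034 to 95052222), Fos (−0.81 ± 0.14), Btg2, Klf4 and Junb had a more negative PM effect, and 11 adjusted over the list alone (camera adjusted p = 3.35e-06, adjusted p = 0.717 with an estimated correlation). Without vehicle PBS 3 there were 9. Cell division genes had a more positive effect as a list (median 0.483; camera adjusted p = 4.02e-10, adjusted p = 0.717 with an estimated correlation). Their calls were 0 of 45 by edgeR, 18 adjusted over the list alone, 28 unadjusted and 1 by DESeq2, with 20 without vehicle PBS 4. Cholesterol genes had a more negative effect (median −0.292; camera adjusted p = 7.94e-07, adjusted p = 0.717 with an estimated correlation). Of these 24, 0 were called by edgeR, 8 adjusted over the list alone, 12 unadjusted and 2 by DESeq2, and 4 without metformin PM 3. NRF2 targets did so too (median −0.144; camera adjusted p = 5.22e-06, adjusted p = 0.717 with an estimated correlation), with Slc7a11 called, 8 adjusted over the list alone and 3 called without vehicle PM 3. Of 16 metal-responsive genes Ndrg1, Slc30a1 (1.26 ± 0.23) and Mt2 (0.82 ± 0.16) had a more positive effect and Tfrc a more negative one (−1.05 ± 0.18), or 4 and 2 adjusted over the list alone (camera adjusted p = 0.463). Ccl9 and Ccl2 were the cytokine and chemokine members called, 4 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.717 with an estimated correlation), and that list was not called without vehicle PBS 3 (0.098). Among coagulation genes Plaur (ENSMUSG00000046223; chromosome 7, 24462500 to 24475873) differed by 0.73 ± 0.11, with 3 adjusted over the list alone (camera adjusted p = 0.275; 2 without metformin PBS 1). Endoplasmic reticulum stress genes shifted upward (median 0.129; camera adjusted p = 0.00318, adjusted p = 0.798 with an estimated correlation; not called without metformin PBS 3, 0.252). Among them 0 of 24 were called by edgeR or DESeq2, 0 adjusted over the list alone, 5 unadjusted and 4 without metformin PBS 1. The 7 neutrophil markers shifted upward with Trem1 called (0.52 ± 0.10; 1 adjusted over the list alone; camera adjusted p = 0.0259, adjusted p = 0.65 with an estimated correlation). That call was lost without vehicle PBS 3 (0.0511), metformin PBS 4 (0.0754), vehicle PM 1 (0.0524) or metformin PM 4 (0.0611). Endothelium and fibroblast markers shifted with these groups (median 0.828; camera adjusted p = 3.38e-06, adjusted p = 0.717 with an estimated correlation), with Bgn (2.28 ± 0.53) and Sparcl1 (1.76 ± 0.42) called and 6 adjusted over the list alone. None was called without vehicle PBS 2, metformin PBS 1, metformin PBS 4, vehicle PM 1, vehicle PM 2, metformin PM 1 or metformin PM 4, 1 without vehicle PBS 1 and 4 without vehicle PM 3. With limma-voom none was called, with the replicate block 1 and with no filter 6.

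**Figure D5:**
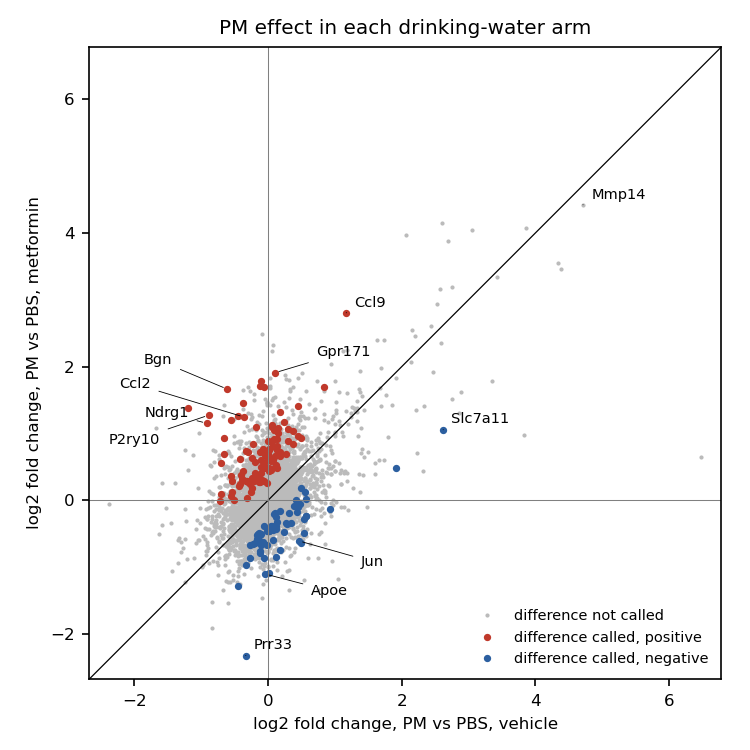
Each point is 1 of 11906 genes, placed by its log2 fold change with PM in animals on vehicle and in animals on metformin, and genes whose difference was called are red where it was positive and blue where it was negative. The diagonal marks equal effects, and the Pearson correlation across genes is 0.4828.

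Across genes, the PM effects in the drinking-water arms correlated with Pearson's r = 0.4828 (Spearman's rho = 0.3792), and 64.29% of genes had the same sign; genes are not independent replicates, and the arms shared no library. In both arms 185 genes rose, where independent lists would share 22.2, and 123 fell, against 15.1. The metformin effects in PBS and PM animals correlated less (r = 0.2414, rho = 0.2952), with 49 shared rises (5.51 for independent lists) and 34 shared falls (6.45). Averaged over the drinking water, PM was followed by 1027 higher and 924 lower genes (edgeR adjusted p under 0.05), with Mmp14 (4.57 ± 0.28), Met (3.97 ± 0.27) and Ass1 (3.95 ± 0.22) among the largest rises. Esrrg (−1.14 ± 0.16) and Rhob (−0.87 ± 0.07) were among the largest falls. Higher genes made up 52.64% of these calls, but 45.52% of 1955 calls with library totals as the only scaling, 49.03% with the stricter filter and 49.55% with thinning to equal totals. For PM with vehicle the share was 53.46%, 47.13% with library totals and 48.62% with the stricter filter, and for PM with metformin 56.18% and, with library totals, 49.5%. Which direction held more genes thus depended on these settings. All tested panel genes other than Tiparp, Stim1 and Orai1 were called there. Ccl2 lost its call with DESeq2 (0.445) or without metformin PBS 1 (0.391), vehicle PM 1 (0.419), vehicle PM 3 (0.377) or metformin PM 4 (0.402), and Srxn1 without 9 of the 13 libraries (0.184 to 0.253). Of the 31 lists tested 20 were called with PM, and 0 with an estimated correlation. The NF-kB targets rose in 22 of 24 cases, also 22 adjusted over the list alone (camera adjusted p = 3.12e-16, adjusted p = 0.0895 with an estimated correlation). Averaged over the instillate, metformin was followed by 644 higher and 644 lower genes, with Hspa1b (2.63 ± 0.26), Hspa1a (2.02 ± 0.22) and Hsph1 (1.30 ± 0.13) among the largest rises. Batf3 (−1.04 ± 0.17), the replication checkpoint gene Clspn (−0.81 ± 0.10) and the mitotic kinase gene Plk1 (−0.77 ± 0.12) were among the largest falls. Of the panel Ccl2 (0.51 ± 0.13), Orai1 (0.29 ± 0.06) and Slc7a11 (0.60 ± 0.15; not called with DESeq2, 0.592) were called. There were 4 lists called, and 0 with an estimated correlation. Of the AMPK and mTOR genes 2 rose, also 2 adjusted over the list alone and 1 with DESeq2 (camera adjusted p = 0.395). There was 1 rise without vehicle PBS 1, vehicle PBS 2, metformin PBS 3 or vehicle PM 1 and 0 without metformin PBS 4 or metformin PM 1. Heat shock genes were higher in 13 of 17 cases, and 15 adjusted over the list alone (camera adjusted p = 1.41e-14, adjusted p = 0.442 with an estimated correlation). Endoplasmic reticulum stress genes were so in 12 of 24 cases, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.68e-06, adjusted p = 0.775 with an estimated correlation). MHC class II genes were higher in 6 of 12 cases, and 9 adjusted over the list alone (camera adjusted p = 1.94e-05, adjusted p = 0.442 with an estimated correlation). Cell division genes were lower in 39 of 45 cases, and 42 adjusted over the list alone (camera adjusted p = 6.08e-23, adjusted p = 0.561 with an estimated correlation). Of the 1951 genes of the averaged PM effect, 1357 (69.55%) had the larger effect in animals on metformin, with a median size of 0.338 against 0.213 on vehicle. The difference itself was called for 115 of them, 100 with the larger and 15 with the smaller effect in animals on metformin. A PBS level that differs between the arms enters such differences too, as for Ccl9 (43.2 CPM with metformin and PBS, 93.2 with vehicle and PBS). Moving labels did not settle whether chance accounts for the differences called.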

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

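Tests of the heat shock pattern against stress of the cells and of the endothelial pattern against a lower macrophage share were chosen only after the results were seen. A library was singled out where its distance from the others exceeded the critical value of Dixon's test for 4 values. This was checked for 147 quantities in the 1 group of 4 libraries, chance alone singles out about 1 in 20, and 8 were found. In vehicle PBS 4 the total was 5.567 M counts (others 6.258 to 6.362), the mitochondrial share 0.9485% (1.004 to 1.015) and Hmcn1 17.86 CPM (8.705 to 10.18). In vehicle PBS 3 the mean of the immediate early genes was 0.3 (others −0.126 to −0.079) and Ddit3 was at 8.29 CPM (5.484 to 5.717). In vehicle PBS 1 the mean of the lymphocyte markers was −0.635 (others 0.156 to 0.301), Stim1 was at 106.7 CPM (97.19 to 98.39) and Hspa1a at 3.957 CPM (8.928 to 9.111).

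Other results stand here because the PM effect differed between the drinking-water arms by the test of the difference itself, as it did for 171 genes. The log2 differences among named genes were 2.16 for P2ry10, 2.07 for Ndrg1, 1.81 for Gpr171, 1.75 for Nr4a3, 1.72 for Crem, 1.64 for Ccl9, 1.60 for Ccl2, 1.26 for Dusp16, 1.15 for Depdc1a and 0.82 for Mt2. They were 2.28 for Bgn, 1.88 for Col4a1, 1.83 for Timp3, 1.83 for Ltbp4 and 1.76 for Sparcl1, genes of vessels and matrix. Negative ones were −1.99 for Prr33, −1.56 for Slc7a11, −1.43 for Cyfip2, −1.13 for Gdf15, −1.10 for Ptpro, −1.06 for Apoe, −1.06 for Jun, −1.05 for Tfrc, −1.03 for Junos, −0.97 for Zfp217, −0.92 for Bhlhe41 and −0.83 for Rhob. By list, the median differences were 0.828 for endothelium and fibroblast markers, 0.483 for cell division genes, 0.39 for neutrophil markers, 0.21 for cytokines and chemokines, 0.129 for endoplasmic reticulum stress genes, −0.144 for NRF2 targets, −0.292 for cholesterol genes and −0.444 for immediate early genes.

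Heat shock genes were higher with metformin in PBS and in PM animals, so the drug is the biological explanation the design gives. Processing order could not be told apart from group, so it stays open beside the drug. Stress of the cells during dissociation and sorting would raise immediate early genes with them. Their median change with metformin was 0.108 in PBS animals (mean 0.093 ± 0.038, SE over genes), which this explanation allows, and −0.289 in PM animals (−0.263 ± 0.074). PM raised these genes in animals on vehicle, with a list mean of 0.417 above vehicle PBS. On metformin the list means above vehicle PBS were 0.108 with PBS and 0.169 with PM, and the list was not called with PM in that arm. A smaller PM response on metformin would give that fall with or without such stress, so in PM animals this test cannot decide. A single library that stands apart was tested by the fewest heat shock genes called when each library was left out. In PM animals these were 11, against 12 with all libraries, which argued against it. In PBS animals the 9 calls became 5 without metformin PBS 4 and 12 without metformin PBS 3. That met the bound set in advance only narrowly, so in PBS animals it argues only weakly against a single library.

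Endothelium and fibroblast markers were higher with PM in the metformin arm. Cells or RNA from lung endothelium and fibroblasts would bring other genes of those cells. Of 33 further genes, picked before they were looked at, the 19 that passed the filter on low counts had a median change of 0.809. Of these 7 were called higher, 10 adjusted over the list alone (camera p = 5.67e-05, p = 0.0947 with an estimated correlation), as this explanation needs. A low gene can pass that filter through the metformin PM libraries alone, so the 19 may lean to genes high there. A lower share of alveolar macrophages in the sort would raise the markers of other cells. The epithelium list rose too (mean 0.484 ± 0.155, SE over genes), and the mean of the endothelium and fibroblast list exceeded it by 0.545 ± 0.185 (SE over genes). That gap counts against the explanation only if all other cells would rise alike, which was not measured, and genes are not independent replicates. This test therefore cannot decide. Whether metformin with PM changed endothelium and fibroblasts in the lung or their carry-over in the sort was not tested.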

How the results depend on the processing

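With 3 or 4 animals a group, counts of called genes depended on single libraries. Leaving out 1 library gave 359 to 584 genes for PM with vehicle, 884 to 1666 for PM with metformin, 121 to 503 for metformin with PBS, 419 to 629 for metformin with PM and 113 to 262 for the difference, and the cause was not tested. With no filter, and so more genes tested, metformin with PBS gave 813 and the difference 507, and with only the groups compared, and so fewer libraries, metformin with PBS gave 200. With the replicate numbers as a block, metformin with PM gave 535 and metformin averaged over the instillate 729. That pairing had little ground, since 1 of 16 pairs with the same number correlated over 0.1 (−0.102 to 0.116), and 2 of 47 other pairs did (−0.143 to 0.141).

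With an estimated correlation 0 lists were called in each of the 7 comparisons (PM with vehicle 0, PM with metformin 0, metformin with PBS 0, metformin with PM 0, difference 0, PM averaged 0, metformin averaged 0). Fry called 10 lists for PM with vehicle, 1 for metformin with PBS, 2 for metformin with PM and 1 for the difference. Among genes with a mean of 5 CPM or more the correlation of the metformin effects with PBS and with PM was 0.3519. Without 1 library, uncalled genes turned direction: Il6, metformin effect with PBS, ranged from −0.258 to 0.63, and Il6, difference of the PM effect between metformin and vehicle, from −0.848 to 0.034, and Tnf from −0.277 to 0.552 for the difference. Of the values of named genes, 357 of 376 kept direction and side of the threshold with DESeq2, 373 of 378 with library totals, 348 of 378 with the block, 364 of 378 with thinning to equal totals, chosen after the data were seen, and 2787 of 3120 without 1 library (325 weaker, 8 reversed). Thinning thus changed few of these calls.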

Other observations

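Genes of the daily clock and glucocorticoid-induced genes were looked at because Per1 (0.85), Fkbp5 (0.86) and Bhlhe41 (−0.92), all controlled by such signals, were among the genes whose PM effect differed. These 3 genes were picked after their values were seen, and the lists below were written before their values were. The p values of these 10 list tests are not adjusted for their number. With PM in animals on vehicle 2 of 12 clock genes rose, Per2 (0.60 ± 0.15) and Nr1d2 (1.004 ± 0.119), and 5 were called adjusted over the list alone (median 0.404; camera p = 0.000638, p = 0.0405 with an estimated correlation). With an estimated correlation the clock list had p = 0.161 for PM with metformin, p = 0.246 for metformin with PBS, p = 0.795 for metformin with PM and p = 0.482 for the difference. Camera counts direction, so members that move in opposite directions cancel in these p values. With PM in animals on metformin 4 of 7 glucocorticoid-induced genes rose, also 4 adjusted over the list alone (median 0.282; camera p = 0.00626, p = 0.042 with an estimated correlation). In the difference of the PM effects 2 of the 7 were called, Tsc22d3 (0.61 ± 0.12) and Klf9 (0.60 ± 0.14), and 3 adjusted over the list alone (median 0.165; camera p = 0.00893, p = 0.0497 with an estimated correlation). For PM with vehicle, metformin with PBS and metformin with PM the glucocorticoid list had p = 0.496, p = 0.631 and p = 0.0711 with an estimated correlation.

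The hypothesis that the metformin PM animals were harvested at another hour was tested by the clock genes in the metformin effect with PM. Of 12 genes 1 was called, and 4 adjusted over the list alone, and members went both ways (0.48 ± 0.117 for Arntl and −0.725 ± 0.245 for Tef). The test is set on sizes without sign, so opposite directions do not count against the hypothesis. The bound set before these values were seen, at most 1 gene called and a median size under 0.3, was met, and taken as it stood it argued against the hypothesis. The median size of 0.256 has a standard error of 0.075, however, so it does not clear the bound by more than its spread. That requirement was applied only after the values were seen, and with it this test could not decide the hypothesis. The hypothesis of a glucocorticoid response was tested by the glucocorticoid-induced genes in the same comparison, whose median was 0.171 with 2 of 7 called, and it could not decide that either. The median size of the clock genes was larger, 0.404, for PM with vehicle, a comparison without metformin PM libraries. Nr1d2 (1.004 ± 0.119) and Per2 (0.597 ± 0.154) were called higher there. Tef (0.799 ± 0.237) and Nr1d1 (0.738 ± 0.262) were higher but not called. Arntl (−0.157 ± 0.116) and Cry1 (−0.127 ± 0.107) were lower, also not called. Whether the vehicle PM or vehicle PBS animals were harvested at another hour was not tested.

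Whether chance could account for the number of calls was tested by moving the group labels between libraries, tests chosen only after the results were seen. For PM with vehicle the real labels gave 578 genes and the highest other split 143. Only 1 of 35 splits was as large, the smallest share possible, so chance can be excluded at that level. The shares here are not adjusted for the number of tests, and moving labels cannot separate group from processing order. For metformin with PBS the real labels gave 365 against 342, also with 1 of 35. The split with 342 set vehicle PBS 1, 2 and 3 against the metformin PBS libraries and the remaining vehicle PBS library. It thus kept most of the real grouping, so its size does not show what chance alone gives. By the share alone chance is excluded at the same level as for PM with vehicle. How far the real count exceeds chance was not settled. The 121 to 503 calls when 1 library was left out show dependence on single libraries and do not measure chance. For PM with metformin (1522 against 0) and metformin with PM (820 against 0), each with 1 of 10 splits as large, the splits are too few for a share under 0.05. For the difference of the PM effects 6 of 100 splits, the real one included, reached the real 171 genes, and the highest other gave 1338. The other 5 move most or all of the PM and PBS labels of an arm, which turns its PM effect over, in part or whole, and brings the PM effect itself into the tested difference. Their size points to that structure of the samples, so these splits do not settle whether chance accounts for the 171 genes. For the averaged effects 1 of 100 splits was as large, with 1951 genes against 1346 for PM and 1288 against 477 for metformin, and so chance can be excluded at that level, before adjustment for the number of tests. The same held for the correlation of the PM effects (0.4828 against 0.4184) and of the metformin effects (0.2414 against 0.1981), each with 1 of 100.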
